A study of Homo sapiens with 10 samples.

How the data were processed

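RNA of 3 tumor cell lines was measured on Affymetrix U133 Plus 2.0 arrays, which carry 54675 probe sets, with 10 arrays in all. Per the submitters' processing notes, the authors computed signals with the MAS5 algorithm, and the label descriptions name the GCOS 1.2 software. Every array had been scaled by the authors to the same trimmed mean. The deposited unit, which the authors give as signal, is a linear intensity, and no step was taken to undo their scaling. Treatments, dose, times and cell lines were taken from the labels.

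Each value was used as log2(value + 16). Probe sets were mapped to genes with the array annotation of the reference set: 41091 carried 1 gene symbol, 1801 several, 11721 none and 62 were controls, and no symbol needed updating. For each of 19775 genes the probe set with the highest mean over the 10 arrays was kept, and 9888 genes with a mean signal of at least 70.1 were tested. Probe sets for several genes or none were left out of the tests, so genes that the annotation does not name were not analysed here. No genome build is attached to the values, so no positions are given.

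The 9 mock, PEP008 24 h and PEP008 recovery arrays were fitted with limma (lmFit and eBayes without a trend) with cell line as a block, which left 4 residual degrees of freedom and a prior of 3.619. Adjusted p is that of Benjamini and Hochberg over the 9888 genes within each of 3 comparisons, two-sided, with a threshold of 0.05, and "passed" refers to it. The pairing of arrays by line comes from the labels. As a check of it, log2 signals correlated across probe sets at 0.939 to 0.977 between arrays of the same line and at 0.820 to 0.880 between lines. A gene was also counted as at least 2-fold in all 3 lines, beside the number expected if the lines were independent.

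Gene lists numbering 22, each with at least 5 measured genes, were fixed before the data were examined, as were the groups, the tests and the alternatives. They covered DNA replication, mitosis, G1/S regulators, CDK inhibitors, p53 targets, secreted factors, senescence chromatin, immediate-early and MAPK feedback, NF-kB targets and diacylglycerol receptors. They also covered interferon-stimulated genes, lysosome, the BCL2 family, mesenchymal genes, integrins, cholesterol synthesis, ATF4 and the unfolded protein response, pigment cell, luminal and colon genes, other cell types and ribosomal proteins. They were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within each comparison. The median of a list is over the fitted log2 changes of its members.

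Genes were named by a rule fixed in advance: the 10 largest rises and 10 largest falls that passed in the same direction in all lines, 4 members per list, and the 5 largest differences per line and direction, or 10 for TPA. In recovery against 24 h, where none passed, genes were ranked by the smallest change among the 3 lines. A further 12 genes, among them CDKN1A, MKI67 and IL6, were named whatever their values.

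Single lines and TPA had 1 array per condition and no test of their own. Their list medians were ranked among 10000 random lists matched in size and expression (20 bins). Intervals for TPA minus PEP008 take the residual spread of the 9-array fit, at a confidence level of 95%, and the limma count with that spread was an alternative. That spread is between lines and exceeds the noise between 2 arrays of a line. Because TPA and PEP008, and the 24 h and recovery arrays of a line, share a mock, 100 simulations of unchanged arrays against a shared mock gave the correlation and overlap to compare with. They drew on the same spread, so their covariance and overlap of 2-fold genes may be too large for arrays of 1 line. With no gene changed, they cannot show what a shared mock adds to an overlap of genes that passed.

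The procedure was tested on simulated data in which 200 of 9888 genes were given a change. It recovered 20% of changes of 1 on the log2 scale, 96% of those of 2, 98% of those of 3 and 100% of those of 4, and called 12 unchanged genes. In the simulated list test, whose genes were drawn as independent, the 1 shifted list was called and 0 of the others. The estimated correlation within the real lists ran from -0.0033 for the BCL2 family to 0.899 for ribosomal proteins. False calls from correlated genes were thus not checked. The number of arrays limits the precision, and changes near 2-fold would mostly be missed.

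Alternatives were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, other filters on dim genes, the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at, no cell line block, an intensity trend, only the 6 arrays of a comparison, and each line left out. Scaling to the hybridisation controls was added after the data were seen. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1.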

Results

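Gene expression was measured on 10 Affymetrix U133 Plus 2.0 arrays of 3 established human tumor cell lines: SK-MEL-5 (melanoma), MCF7 (breast cancer) and COLO-205 (colon cancer). Each line gave 1 array of cells mock treated with solvent for 24 h, 1 array after 24 h of PEP008 at 1000 ng/ml, and 1 array after the same exposure followed by drug removal and 72 h of recovery. SK-MEL-5 gave 1 further array after 24 h of TPA at the same dose. Per the labels, PEP008 is 20-O-acetyl-ingenol-3-angelate and TPA is 12-O-tetradecanoylphorbol-13-acetate, and the series title names growth arrest resembling senescence as its subject. The mock, 24 h and recovery groups thus held 3 arrays each and the TPA group held 1. The replicates were cell lines with 1 array per line and condition and no separate cultures, so each p measures the spread of the response between lines. The median signal of the arrays lay between 20.05 and 28.99, and the ratio of 3' to 5' GAPDH control signal, a sign of RNA integrity, lay between 0.897 and 0.969. The number of arrays limited the precision, with a median standard error of 0.248 on the log2 scale for a change over 3 lines.

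The comparison of PEP008 at 24 h with mock addresses which genes respond to the drug before it is removed. The genes that fell in all 3 lines included TYMS and GINS1, which serve DNA synthesis, and KIF11 and ASPM, which serve mitosis, and those that rose included S100A2, SERPINE2 and the laminin chain LAMB3. S100A2, a calcium-binding protein of epithelial cells, rose 13.8-fold (log2 change 3.79 ± 0.22 SE, n = 3 lines, adjusted p = 0.00256), by 3.81 in SK-MEL-5, 3.81 in MCF7 and 3.75 in COLO-205. Its mock signals of 12.7 in SK-MEL-5 and 21.4 in MCF7 were dim, so the size of the rise and the closeness of the lines depend on the pseudocount of 16: the log2 change was 4.42 with a pseudocount of 1 and 2.87 with 64, and S100A2 passed with both. SERPINE2, a secreted serine protease inhibitor, rose 10.1-fold (3.33 ± 0.47, adjusted p = 0.0327). TYMS, the enzyme that makes thymidylate for DNA synthesis, fell by 3.17 on the log2 scale (SE 0.53, adjusted p = 0.0418), and the mitotic motor KIF11 fell by 2.79 (SE 0.30, adjusted p = 0.0327). Of 9888 genes tested, 38 rose and 123 fell, each in the same direction in all 3 lines. The hybridisation controls were 0.54 higher on the log2 scale at 24 h than in mock in SK-MEL-5 and 0.50 higher in COLO-205, and scaling to them gave 28 rises and 359 falls. The poly-A control dap (3' probe set) did not follow them in SK-MEL-5, with a signal of 1367 in mock and 1393 at 24 h. It read 873 and 1019 in MCF7 and 1118 and 1542 in COLO-205.

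The other large rises were those of GEM, a small GTPase (2.99 ± 0.55), PMEPA1, an inhibitor of TGF-beta signalling (2.96 ± 0.32), PLAUR, the urokinase receptor (2.85 ± 0.50), and LAMB3, a laminin chain (2.67 ± 0.42). IRAK2, a kinase of interleukin-1 signalling, rose by 2.46 ± 0.37, and ISM1, a secreted protein, rose by 2.41 ± 0.42. TNFRSF12A, the receptor of the cytokine TWEAK, rose by 2.32 ± 0.31, and DUSP4, a phosphatase that switches off MAP kinases, rose by 2.09 ± 0.35. The other large falls were those of E2F8, a repressor of the cell cycle transcription program (-3.03 ± 0.47), DEPDC1 (-2.79 ± 0.39), GINS1 of the replicative helicase (-2.75 ± 0.48), the spindle gene ASPM (-2.72 ± 0.27) and the histone chaperone ASF1B (-2.68 ± 0.38). NDC80 of the kinetochore fell by 2.64 (SE 0.38), the DNA repair gene RAD51AP1 fell by 2.64 (SE 0.48), and the mitotic kinesin KIF20A fell by 2.58 (SE 0.36). Adjusted p for these genes lay between 0.0327 and 0.0494. Several had signals near or below the pseudocount of 16 on some arrays, and their sizes depend on it: with pseudocounts of 1 and 64 the log2 change was 3.56 and 1.45 for ISM1, 3.48 and 1.96 for LAMB3, 2.95 and 1.74 for IRAK2, and -3.56 and -2.25 for E2F8. None of these 4 passed with a pseudocount of 1.

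**Figure D1:**
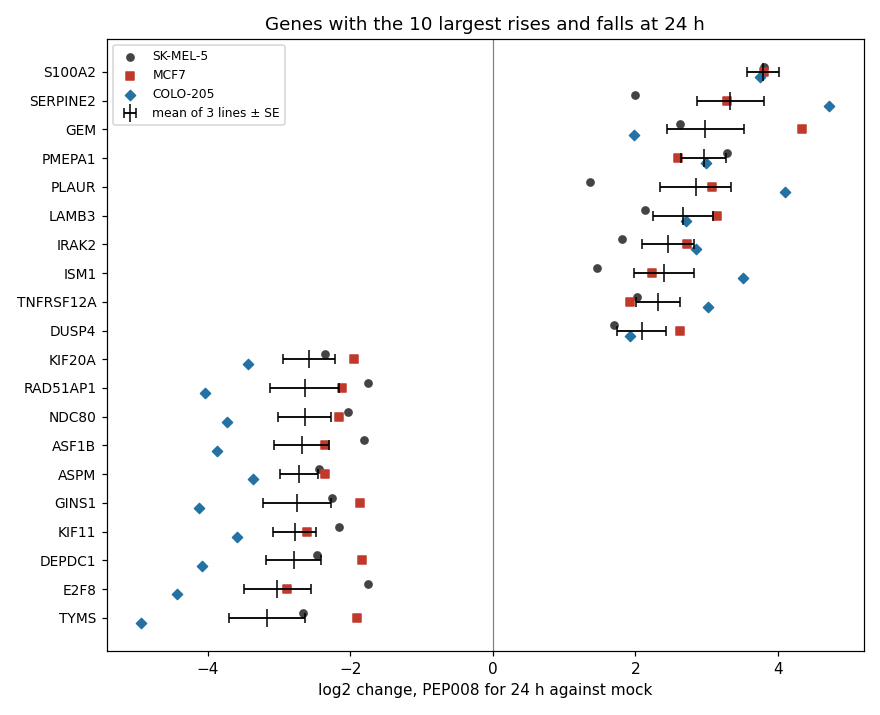
Log2 change from mock to 24 h of PEP008 (horizontal axis) for the genes with the 10 largest rises and the 10 largest falls among those that passed the test. Points are single lines, 1 array against its mock, and bars are the mean of the 3 lines ± SE; the 3 points of S100A2 lie between 3.75 and 3.81, while those of TYMS reach -4.93 in COLO-205.

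Among the gene lists fixed in advance, those of cell division moved furthest at 24 h by the median of the fit over the 3 lines. In MCF7 alone the secreted factors, with a median of 2.53, moved further. Of 37 measured DNA replication genes 13 fell and 24 did not pass, and 36 fell when adjusted over the list alone (median log2 change -1.83, camera adjusted p = 3.84e-27, adjusted p = 0.274 with an estimated correlation). The list included CDT1, which loads the helicase (-2.53 ± 0.38), and GINS2 (-2.51 ± 0.46). Of 41 mitosis genes 24 fell, and 39 when adjusted over the list alone (median -2.27, adjusted p = 4.47e-35, and 0.265 as adjusted p with an estimated correlation). The medians of both lists were deepest in COLO-205, at -2.92 for DNA replication and -3.39 for mitosis, against -1.10 and -1.34 in MCF7 and -1.41 and -2.10 in SK-MEL-5. MKI67, the proliferation marker of the mitosis list, fell by 2.29 (SE 0.41, adjusted p = 0.0475). Of 14 G1/S regulators, E2F8 and the ubiquitin ligase gene SKP2 (-1.73 ± 0.28) fell and 12 did not pass, with 7 falling when adjusted over the list alone (median -0.70, adjusted p = 0.000297, adjusted p = 0.352 with an estimated correlation).

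Senescence-associated secreted factors rose as a list (median 1.51, adjusted p = 1.00e-07, adjusted p = 0.265 with an estimated correlation). The line medians were 1.26 in SK-MEL-5, 2.53 in MCF7 and 1.47 in COLO-205. Of its 21 measured members PLAUR and TIMP1 rose (4 when adjusted over the list alone) and 19 did not pass. PLAUR is a cell surface receptor and TIMP1 an inhibitor of metalloproteinases (1.95 ± 0.30), and neither is a cytokine. The chemokine CXCL8 had a log2 change of 3.84 ± 1.27 (adjusted p = 0.189), with 2.81 in SK-MEL-5, 2.68 in MCF7 and 6.02 in COLO-205, and the cytokine IL6 one of 1.66 ± 0.92 (adjusted p = 0.418), with 1.26 in SK-MEL-5 and 4.14 in MCF7. IL6 signals in COLO-205 were 8.36 in mock, 2.21 at 24 h and 6.90 after recovery, below the minimum of 70.1, so no change can be read there. Among 14 senescence chromatin genes EZH2, the methyltransferase of Polycomb complex 2, fell by 1.63 (SE 0.24), and 2 rose and 7 fell when adjusted over the list alone (median -0.57, adjusted p = 0.00297, adjusted p = 0.352 with an estimated correlation). LMNB1, the nuclear lamina protein lamin B1, had a change of -1.99 ± 0.47 (adjusted p = 0.0837). The call of the chromatin list was lost without SK-MEL-5 (median -0.44, adjusted p = 0.0808).

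Integrins and cell adhesion had 4 of 16 members rise (6 when adjusted over the list alone), namely LAMB3, ITGA3 (1.80 ± 0.29), ITGB5 (1.78 ± 0.26) and ITGA5 (1.55 ± 0.27), with a median of 0.96 (adjusted p = 7.72e-08, adjusted p = 0.186 with an estimated correlation). The median of that list was 1.48 without SK-MEL-5. Immediate-early and MAPK feedback genes had a median of 0.79 (adjusted p = 1.00e-07, adjusted p = 0.223 with an estimated correlation), or 0.51 without MCF7, and of its 29 members DUSP4 rose, or 5 when adjusted over the list alone. EGR1 had a change of 0.93 ± 0.78 (adjusted p = 0.5997), with 3.32 in MCF7, -0.49 in SK-MEL-5 and -0.04 in COLO-205, and -0.27 without MCF7, and DUSP6 one of 1.71 ± 0.93 (adjusted p = 0.411), which was 5.06 in MCF7, -0.20 in SK-MEL-5 and 0.27 in COLO-205. NF-kB targets had a median of 1.06 (adjusted p = 0.00083, adjusted p = 0.352 with an estimated correlation), and none of 19 members passed, nor when adjusted over the list alone; the largest changes were those of CXCL8 and CCL20 (3.10 ± 1.28).

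Smaller list shifts at 24 h were those of the lysosome (median 0.34, adjusted p = 0.000648, adjusted p = 0.382 with an estimated correlation) and the BCL2 family (0.34, 0.00149 and 0.223 in the same order). In the lysosome list the protease gene CTSL rose (1.38 ± 0.26; 1 of 20, and 3 when adjusted over the list alone), and the list's median was -0.01 without COLO-205 (adjusted p = 0.0763). None of 17 BCL2 family members passed, and 1 did when adjusted over the list alone, with CFLAR at 1.11 ± 0.24 (adjusted p = 0.0662); the median was 0.19 without COLO-205 and 0.53 without SK-MEL-5. Interferon-stimulated genes had a median of 0.31 (adjusted p = 0.0411, adjusted p = 0.497 with an estimated correlation), none of 16 passed, 1 rose when adjusted over the list alone, and the median was 0.05 without COLO-205 (adjusted p = 0.519) and 0.60 without MCF7. The largest change in it was that of the exonuclease gene ISG20 (3.06 ± 0.66, adjusted p = 0.0662). Cholesterol synthesis genes had a median of -0.61 (adjusted p = 0.00278, adjusted p = 0.352 with an estimated correlation), and none of 11 passed, nor when adjusted over the list alone. INSIG1, a sterol sensor, had a change of -1.44 ± 0.55, and the median of the list was -0.37 without COLO-205 (adjusted p = 0.0563) and -0.92 without SK-MEL-5.

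The remaining 10 lists did not pass at 24 h. CDK inhibitors had a median of 0.33 (adjusted p = 0.136) and none of 10 members passed; CDKN1A, which encodes the CDK inhibitor p21, had a change of 1.4998 ± 0.45 (adjusted p = 0.159), with 0.08 in SK-MEL-5, 2.40 in MCF7 and 2.02 in COLO-205. Of 23 p53 targets the DNA damage recognition gene DDB2 fell by 2.14 (SE 0.29), the same 1 gene when adjusted over the list alone (list median 0.36, adjusted p = 0.571). The p53 median was -0.05 without MCF7 and -0.07 without COLO-205. Diacylglycerol and phorbol ester receptors had a median of 0.10 (adjusted p = 0.501), with RASGRP1 at -1.29 ± 0.25 (adjusted p = 0.0553, falling when adjusted over the list alone) and PRKCA at 0.32 ± 0.25. As fixed, that list also held genes that are not such receptors, such as PRKCI, PRKCZ and MARCKS. Its median need not be one of receptors alone. Of 13 mesenchymal genes ITGA5 rose (median 0.29, adjusted p = 0.0716). ATF4 and unfolded protein response genes had a median of -0.22 but a mean of 0.05 and an upward test (adjusted p = 0.388). Markers of lineage did not pass as lists, with pigment cell genes at -0.34 (adjusted p = 0.264), luminal breast and estrogen response genes at -0.39 (adjusted p = 0.0646) and colon epithelial genes at 0.29 (adjusted p = 0.417). These tests average over 3 lines, so they cannot show a change limited to the line of that lineage. The median was -0.48 for pigment cell genes in SK-MEL-5, -0.70 for luminal genes in MCF7 and 0.42 for colon genes in COLO-205, without a test. MITF, the pigment cell regulator, had a change of 0.44 ± 0.83, which was -0.90 without MCF7, and ESR1, the estrogen receptor, one of -1.21 ± 0.48 (adjusted p = 0.257), with a signal in MCF7 of 1992 in mock and 251 at 24 h. CCND1, the cyclin that starts G1 progression, had a change of 1.54 ± 0.58 (adjusted p = 0.238). Ribosomal proteins had a median of 0.06 (adjusted p = 0.497), and markers of blood, fibroblast and endothelial cells one of -0.13 (adjusted p = 0.945). CDX2 was below the signal minimum on every array (highest signal 16.6).

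COLO-205 decided several of these results. Without it the ATF4 list had a median of 0.53 (adjusted p = 0.001375), the luminal list one of -0.59 (adjusted p = 0.001375) and the ribosomal list one of 0.15 (adjusted p = 0.0424), and without SK-MEL-5 the luminal list had -0.54 (adjusted p = 0.0413). In all, camera called 12 of 22 lists at its preset correlation and 0 with an estimated correlation. The fry test, which asks whether a list moves on balance in 1 direction, called only integrins and cell adhesion (adjusted p = 0.0216).

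In limma the count of 161 genes at 24 h was lost with any line left out. Without SK-MEL-5 2 genes passed, neither of them among the 161, and 0 passed without MCF7 and 0 without COLO-205. Genes at an unadjusted p under 0.05 numbered 1536, 1487 and 961 against 1672 with all lines. Such fits have fewer residual degrees of freedom than the 4 of the full fit, so fewer calls follow whichever line is dropped. Without the cell line as a block 0 genes passed (446 at an unadjusted p under 0.05), and a pseudocount of 1 gave 4.

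The comparison of recovery with mock addresses which changes were present 72 h after the drug was removed. The mock was harvested at 24 h, so time in culture differed as well as drug. The mitotic genes KIF11 and ASPM were still below mock, and the integrin genes ITGA3 and ITGB5 above it. SERPINE2 rose 12.2-fold (3.61 ± 0.47, n = 3 lines, adjusted p = 0.0395), PMEPA1 rose by 2.90 ± 0.32, TNFRSF12A by 2.53 ± 0.31 and CITED2, a transcriptional coregulator, by 2.34 ± 0.23. KIF11 fell by 2.42 (SE 0.30), ASPM fell by 2.39 (SE 0.27) and SKP2 fell by 2.17 (SE 0.28). In all 15 genes rose and 15 fell, every one in the same direction in the 3 lines. Of these, 13 of the 15 that rose and 14 of the 15 that fell had passed at 24 h (0.0576 and 0.187 expected of independent lists). Both comparisons used the same mock arrays, so part of this overlap may come from shared controls. Simulated unchanged arrays sharing a mock gave 0 and 0. With no gene changed almost none can pass, so that simulation cannot show what shared controls add.

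ITGA3 (2.11 ± 0.29) and ITGB5 (2.10 ± 0.26), both integrin subunits, were among the other genes that rose. So were PLD1, a phospholipase (1.96 ± 0.27), QSOX1, a secreted oxidase (1.85 ± 0.25), SLC17A5, a lysosomal sialic acid transporter (1.76 ± 0.24), and the interleukin-4 receptor gene IL4R (1.75 ± 0.23). The other falls were those of FBXO5, an inhibitor of the anaphase-promoting complex (-2.11 ± 0.28), PIMREG (-1.98 ± 0.28), TK1, thymidine kinase (-1.98 ± 0.24), KIF15 (-1.89 ± 0.26), CDCA7L (-1.85 ± 0.21), the lamin B receptor gene LBR (-1.74 ± 0.23) and the centromere gene CENPO (-1.71 ± 0.23). Adjusted p for these genes lay between 0.0395 and 0.0488. The change of ITGA3 was 2.71 with a pseudocount of 1 and 1.31 with 64.

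After recovery DNA replication genes had a median of -1.66 (camera adjusted p = 1.44e-20, adjusted p = 0.237 with an estimated correlation). Of 37 members TK1 alone fell over all genes tested, and 35 fell when adjusted over the list alone. Mitosis genes had a median of -2.02 (adjusted p = 4.98e-27, adjusted p = 0.237 with an estimated correlation), with KIF11 and ASPM falling of 41, and 39 when adjusted over the list alone. The line medians were close together, from -1.59 to -1.69 for DNA replication and from -1.83 to -2.17 for mitosis. MKI67 had a change of -2.12 ± 0.41 (adjusted p = 0.0563). G1/S regulators had a median of -0.59 (adjusted p = 0.000603, adjusted p = 0.256 with an estimated correlation), with SKP2 falling of 14 members, and 1 rising and 7 falling when adjusted over the list alone. CCND1 had a change of 2.11 ± 0.58 (adjusted p = 0.103). CDK inhibitors had a median of 0.60 (adjusted p = 0.028, adjusted p = 0.237 with an estimated correlation), which was 0.18 without COLO-205 (adjusted p = 0.0521) and 0.33 without MCF7. None of its 10 members passed, nor when adjusted over the list alone; CDKN1A had a change of 1.48 ± 0.45 (adjusted p = 0.122; 1.26 in SK-MEL-5, 2.10 in MCF7 and 1.09 in COLO-205), and CDKN1C, which encodes the inhibitor p57, one of 1.94 ± 1.03, of which COLO-205 had 5.41.

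Secreted factors had a median of 2.24 after recovery (adjusted p = 8.32e-09, adjusted p = 0.237 with an estimated correlation), or 1.35 without SK-MEL-5, and none of 21 members passed over all genes, while 6 rose when adjusted over the list alone. CXCL8 had a change of 4.79 ± 1.27 (adjusted p = 0.0968), the collagenase gene MMP1 one of 4.38 ± 1.55, and INHBA, the activin A subunit, one of 4.18 ± 1.30. IL6 had a change of 2.24 ± 0.92 (adjusted p = 0.216), with 4.01 in SK-MEL-5 and 2.79 in MCF7. NF-kB targets had a median of 1.12 (adjusted p = 6.95e-05, adjusted p = 0.256 with an estimated correlation), with 1.88 in SK-MEL-5, 0.36 in MCF7 and 0.38 in COLO-205; none of 19 passed, and 3 rose when adjusted over the list alone. On the SK-MEL-5 recovery array the endothelial marker PECAM1 read 308, against 37.3 in mock and 103 at 24 h. The fibroblast marker DCN read 583 there, against 248 in mock and 149.9 at 24 h, while the fibroblast markers COL1A2, COL3A1 and PDGFRB read 1.41, 1.30 and 6.67, LUM read 2778 against 3956 in mock, and the endothelial markers CDH5 and VWF read 2.30 and 7.83. The list of blood, fibroblast and endothelial markers had a median of 1.02 in SK-MEL-5, -0.30 in MCF7 and 0.44 in COLO-205 and did not pass (median 0.46, adjusted p = 0.297).

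The lysosome list had a median of 0.81 (adjusted p = 8.32e-09, adjusted p = 0.237 with an estimated correlation); none of 20 members passed over all genes and 11 rose when adjusted over the list alone. NPC1, which exports cholesterol from the lysosome, had a change of 1.86 ± 0.35 (adjusted p = 0.0563), and the cathepsin genes CTSL and CTSB had changes of 1.57 ± 0.26 and 1.39 ± 0.30. Integrins and cell adhesion had a median of 1.32 (adjusted p = 7.97e-08, adjusted p = 0.1796 with an estimated correlation), with ITGA3 and ITGB5 rising of 16 members, and 6 when adjusted over the list alone. Immediate-early and MAPK feedback genes had a median of 1.01 (adjusted p = 7.97e-08, adjusted p = 0.225 with an estimated correlation); none of 29 passed and 4 rose when adjusted over the list alone, with the phosphatase gene DUSP5 at 2.73 ± 0.66. EGR1 had a change of 1.04 ± 0.78 and DUSP6 one of 1.35 (adjusted p = 0.437). Senescence chromatin genes had a median of -0.81 (adjusted p = 0.000603, adjusted p = 0.237 with an estimated correlation); none of 14 passed, and 1 rose and 8 fell when adjusted over the list alone. LMNB1 had a change of -2.15 ± 0.47 (adjusted p = 0.0717), and HMGA2, an architectural chromatin protein, one of 2.55 ± 0.66.

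Further lists passed after recovery with no member passing over all genes. The BCL2 family had a median of 0.72 (adjusted p = 0.000594, adjusted p = 0.1796 with an estimated correlation; 0.46 without MCF7), with 2 of 17 rising when adjusted over the list alone and the proapoptotic gene PMAIP1 at 1.36 ± 0.33. Interferon-stimulated genes had a median of 0.68 (adjusted p = 0.001375, adjusted p = 0.278 with an estimated correlation; 0.34 without COLO-205), with none of 16 when adjusted over the list alone. Mesenchymal genes had a median of 0.30 (adjusted p = 0.0206, adjusted p = 0.237 with an estimated correlation), with 3 of 13 when adjusted over the list alone and TGFBI at 1.72 ± 0.42. That call was lost without SK-MEL-5 (0.40, adjusted p = 0.113), and the median was 0.63 without MCF7. For p53 targets the median was 0.24 (adjusted p = 0.0479, adjusted p = 0.494 with an estimated correlation), with none of 23 when adjusted over the list alone and GDF15 at 1.74 ± 0.94. The p53 call was lost without MCF7 (0.04, adjusted p = 0.704), and the median was 0.40 without SK-MEL-5 and 0.48 without COLO-205. Cholesterol synthesis had a median of -0.51 (adjusted p = 0.04735, adjusted p = 0.494 with an estimated correlation), with none of 11 when adjusted over the list alone and INSIG1 at -0.88 ± 0.55; the call was lost without COLO-205 (-0.12, adjusted p = 0.674), and the median was -0.85 without SK-MEL-5. ATF4 and unfolded protein response genes had a median of 0.32 (adjusted p = 0.04735, adjusted p = 0.596 with an estimated correlation), with 2 of 15 when adjusted over the list alone and PPP1R15A at 1.32 ± 0.30. The ATF4 median was 0.35 without SK-MEL-5 (adjusted p = 0.265), -0.30 without MCF7 (adjusted p = 0.645) and 1.09 without COLO-205.

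The lists of diacylglycerol and phorbol ester receptors (median 0.03, adjusted p = 0.707, with RASGRP1 falling when adjusted over the list alone), pigment cell genes (-0.26, adjusted p = 0.30), luminal genes (-0.19, adjusted p = 0.353), colon epithelial genes (0.33, adjusted p = 0.186) and ribosomal proteins (-0.01, adjusted p = 0.925) did not pass after recovery. The pigment cell list had -0.38 without MCF7 (adjusted p = 0.0391) and the ribosomal list 0.16 without COLO-205 (adjusted p = 0.0461). In the line of each lineage the median, without a test, was -0.89 for pigment cell genes in SK-MEL-5. It was -0.39 for luminal genes in MCF7 and 0.18 for colon genes in COLO-205. Of the 22 lists camera called 16 at its preset correlation and 0 with an estimated correlation, and fry called 10. PRKCA had a change of 0.41, MITF of 0.33 (-0.03 with the mean of all probe sets of a gene) and ESR1 of -1.30 ± 0.48 (adjusted p = 0.172). The count of 30 genes also changed with the arrays used and with scale. Limma called 0 genes without any 1 of SK-MEL-5, MCF7 or COLO-205 (1505, 1694 and 1583 at an unadjusted p under 0.05, against 2137). These fits again had fewer residual degrees of freedom. Without the cell line block 0 passed (547), while 163 passed after quantile normalization and 151 after centring each array on its median. Rises went from 15 to 56 and 35 under those 2 scalings and falls from 15 to 107 and 116, so that rises made up 34.4% and 23.2% instead of 50%.

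**Figure D2:**
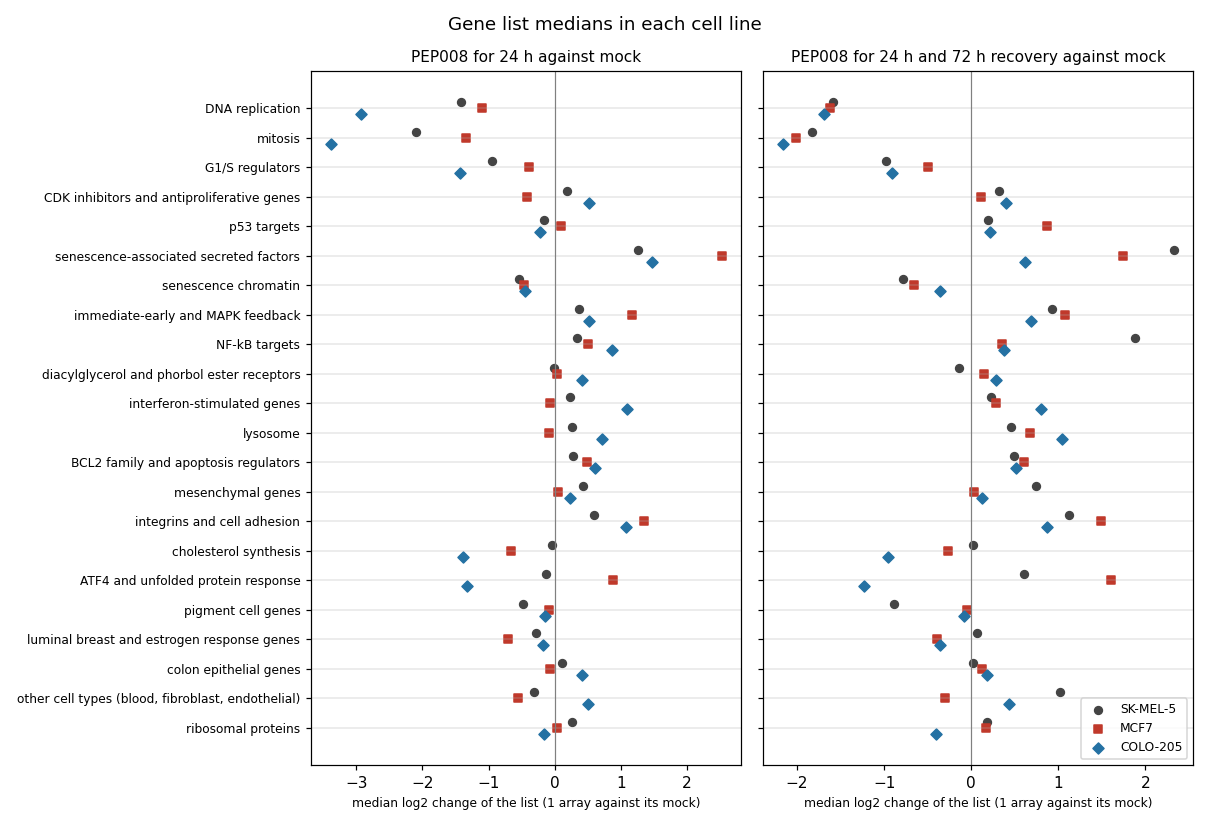
Median log2 change of each gene list in each cell line, 1 array against its mock, at 24 h (left) and after recovery (right). Mitosis medians lie between -1.34 and -3.39 at 24 h and between -1.83 and -2.17 after recovery, and the ATF4 list lies at 1.61 in MCF7 and -1.23 in COLO-205 after recovery.

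The comparison of recovery with 24 h addresses what changed once the drug was taken away. S100A2 had the smallest p, with a log2 change of -2.23 ± 0.22 (n = 3 lines, adjusted p = 0.1225), from a signal of 387 to 49.1 in SK-MEL-5, 509 to 137 in MCF7 and 1608 to 316 in COLO-205. S100A8, another gene of that family, had the largest change, 2.71 ± 0.91 (adjusted p = 0.994), with 5.38 in SK-MEL-5, 1.83 in MCF7 and 0.91 in COLO-205. FUCA1, a lysosomal fucosidase (1.34 ± 0.45), and PIK3IP1, an inhibitor of PI3 kinase (1.46 ± 0.23), were at least 2-fold higher in all 3 lines, and S100A2 was the 1 gene at least 2-fold lower. No gene passed in limma, with 351 at an unadjusted p under 0.05 against 494.4 expected by chance, and every gene but S100A2 had an adjusted p of at least 0.994. MKI67 had a change of 0.16 between the 2 times, LMNB1 one of -0.16 and CDKN1A one of -0.02.

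The lysosome list moved up between 24 h and recovery (median 0.42, camera adjusted p = 7.64e-06, adjusted p = 0.730 with an estimated correlation; 0.25 without MCF7). It had 12 of 20 members higher in all 3 lines, such as the ceramidase gene ASAH1 (1.10 ± 0.39) and the glucosidase gene GAA (0.79 ± 0.26), and 0 that passed, also when adjusted over the list alone. Mitosis genes had a median of 0.28 (adjusted p = 0.00941, adjusted p = 0.730 with an estimated correlation), made of 1.21 in COLO-205, 0.19 in SK-MEL-5 and -0.66 in MCF7. That median was 0.30 without SK-MEL-5 (adjusted p = 0.0745), 0.68 without MCF7 and -0.20 without COLO-205 (adjusted p = 0.00983), so its direction depended on COLO-205. The p53 targets had a median of 0.22 (adjusted p = 0.0251, adjusted p = 0.730 with an estimated correlation), with DDB2 at 1.05 ± 0.29 and TP53INP1 at 0.92 ± 0.67, and the call was lost without SK-MEL-5 (0.23, adjusted p = 0.0838) or MCF7 (0.13, adjusted p = 0.170) while the median was 0.40 without COLO-205. Scaling to the hybridisation controls ended the calls of mitosis (median 0.37) and p53 targets (median 0.32). No member of the mitosis or p53 list passed, also when adjusted over the list alone. The other 19 lists had adjusted p between 0.0508, for DNA replication (median 0.20), and 0.861, for pigment cell genes (0.05). Among these were secreted factors at 0.35, with 2.01 in SK-MEL-5, -0.12 in MCF7 and -0.54 in COLO-205, and NF-kB targets at 0.27 (adjusted p = 0.191). Without SK-MEL-5 the medians of these 2 lists were -0.47 (adjusted p = 0.0293) and -0.47 (adjusted p = 0.012), and the DNA replication median was -0.29 without COLO-205 (adjusted p = 3.03e-05) and 0.63 without MCF7. CXCL8 had a change of 0.96 ± 1.27, IL6 of 0.58 and CCND1 of 0.57.

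The comparison of each line with its own mock addresses how far the 3 tumor types shared their response. It had no test, since each line had 1 array per condition. At least 2-fold changes in the same direction in all 3 lines were seen in 52 genes up and 158 down at 24 h, against 2.87 and 3.70 expected of independent lines, and in 100 up and 223 down after recovery, against 5.71 and 3.60. With the arrays scaled to the hybridisation controls these were 18 up and 216 down at 24 h and 58 up and 310 down after recovery. Across the 9888 genes, which are not independent replicates, the 24 h changes of different lines, each against its own mock, correlated with a mean Pearson r of 0.312 (0.202 to 0.376), and the recovery changes with one of 0.391. Within a line the changes at 24 h and after recovery share a mock, and they had r = 0.810 in SK-MEL-5, 0.721 in MCF7 and 0.893 in COLO-205. The changes averaged over the 3 lines had r = 0.868 between the 2 times with a covariance of 0.337, against 0.499 and 0.0478 for simulated unchanged arrays (100 simulations), a covariance difference of 0.289. Part of each r may come from shared controls.

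Each line also had large changes of its own. Many of these genes had mock signals near or below the pseudocount of 16, such as DLK1, CGA, MMP1, HSD3B1 and MAOB, so that the sizes and the order of their differences depend on it. In SK-MEL-5 at 24 h the largest log2 differences were those of DLK1, a growth regulator of the Notch ligand family (6.16; signal 1.45 to 1228), the glycoprotein hormone STC1 (5.45) and CGA, the alpha subunit of glycoprotein hormones (4.29), with CLDN1 of tight junctions at -3.10 and the hyaluronan synthase HAS2 at -3.07. After recovery CXCL8 stood 7.91 higher than in mock (38.5 to 13099), CCL20 7.34 and PTGS2, cyclooxygenase 2, 7.22. In MCF7 at 24 h MMP1 differed by 8.20 (4.72 to 6059), the steroid enzyme HSD3B1 by 7.20 and INHBA by 6.92, while AGR3 (-5.33), the protocadherin PCDH10 (-4.69) and the GDNF receptor GFRA1 (-4.02) were lower. After recovery the largest values in MCF7 were those of CEMIP, a hyaluronan-degrading protein (7.83), MMP1 (7.67) and S100A9 (7.45). COLO-205 had MMP7 at 6.72, the cornified envelope genes SPRR1B and SPRR3 at 6.66 and 6.02, and CXCL8 at 6.02 at 24 h, with TYMS at -4.93 and RRM2, a subunit of ribonucleotide reductase, at -4.66. After recovery it had MMP7 at 6.60, MAOB at 5.47 and CDKN1C at 5.41 (57.2 to 3094), and CXCR4 at -3.30. From 24 h to recovery RRM2 in COLO-205 differed by 3.01 (signal 230 to 1973, with 6227 in mock), PI3 in SK-MEL-5 by 6.302 and CXCL2 by 5.56, and the pregnancy-specific glycoprotein PSG6 in MCF7 by 4.77.

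**Figure D3:**
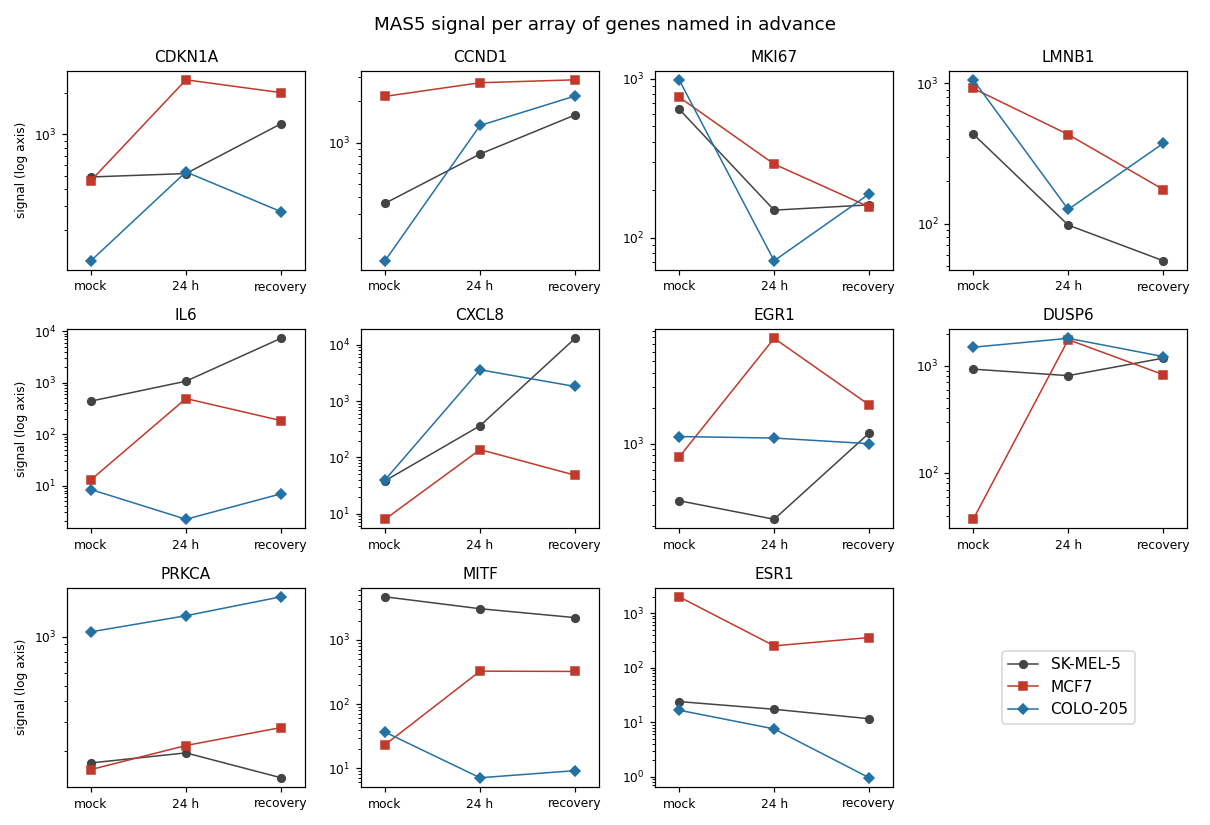
MAS5 signal (log axis) of 11 genes chosen in advance on each mock, 24 h and recovery array of the 3 lines, 1 array per point. MKI67 and LMNB1 lie below mock on every PEP008 array, and CXCL8 in SK-MEL-5 goes from 38.5 in mock to 13099 after recovery.

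The comparison of TPA with PEP008 in SK-MEL-5, at the same dose and time, addresses whether an ingenol ester and a phorbol ester give the same expression response. It had 1 array per compound and no test of its own. Against mock, TPA gave 493 genes at least 2-fold higher and 448 lower, and PEP008 496 and 440, with 363 up and 353 down in common and 0 in opposite directions. The largest TPA differences were those of DLK1 (5.99, against 6.16 with PEP008), STC1 (5.13 and 5.45), the protease inhibitor A2M (3.70 and 3.73) and PAEP (3.40 and 3.53). Next were RAB27B (3.16 and 3.22) and the metallothioneins MT1H (3.22 and 3.41), MT2A (3.02 and 3.06) and MT1X (2.90 and 3.07). Among the largest on the low side were the condensin gene NCAPH (-3.02 and -2.26), CLDN1 (-2.90 and -3.10), DEPDC1B (-2.87 and -3.14), MCM7 of the replicative helicase (-2.70 and -2.37) and ASPM (-2.66 and -2.44).

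List medians of TPA against mock were -2.16 for mitosis and -1.42 for DNA replication, both below all 10000 random lists matched on expression, and 0.88 for secreted factors and 0.56 for integrins, both above all of them. Between the compounds, the median of TPA minus PEP008 was -0.24 for secreted factors (percentile 0.07), -0.22 for NF-kB targets (percentile 0.14), -0.02 for DNA replication (percentile 44.35) and -0.06 for mitosis (percentile 12.12). The random lists treat genes as independent, which members of a list are not, and there was 1 array per compound, so these percentiles are ranks and not tests. The 95% interval of the TPA minus PEP008 difference was -5.78 to 4.44 for CXCL8 and -4.08 to 3.33 for IL6. CXCL8 differed from mock by 2.14 with TPA and 2.81 with PEP008, IL6 by 0.88 and 1.26, MKI67 by -2.24 and -2.00, LMNB1 by -1.66 and -1.99 and CDKN1A by 0.10 and 0.08. Of 9888 genes 96.0% lay within 1.5-fold between the compounds and 65 differed at least 2-fold, 30 higher and 35 lower with TPA. Among genes whose brighter value was at or above the median of the tested genes, MRPL2, a mitochondrial ribosomal protein, had the largest difference (1.45, signal 154 with PEP008 and 449 with TPA, 95% interval 0.37 to 2.53), then the translation factor EIF5A (1.21, interval -0.60 to 3.01), and on the low side GOLGA8N (-1.22, interval -3.04 to 0.59). The intervals take the residual spread of the 9-array fit, which is the spread of the drug response between lines and not the noise between 2 arrays of 1 line, and their median half-width was 0.999. With that spread limma called 0 genes (41 at an unadjusted p under 0.05 against 494.4 expected), a count below chance that does not speak for or against a difference between the compounds. The changes of both compounds correlated across genes with r = 0.909 and a covariance of 0.358, against 0.499 and 0.144 for simulated unchanged arrays sharing the mock, a covariance difference of 0.2145. Part of the excess of shared genes and of r may come from shared controls, for which the simulation gave 86.3 shared rises and 87.1 shared falls. Its arrays were drawn with the same between-line spread, so these counts and the covariance of 0.144 may overstate what a shared mock gives. Across genes the SD of TPA minus PEP008 was 0.268. Against the PEP008 responses of the other lines, which have their own mocks, the TPA change had r = 0.197 in MCF7 and 0.381 in COLO-205.

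**Figure D4:**
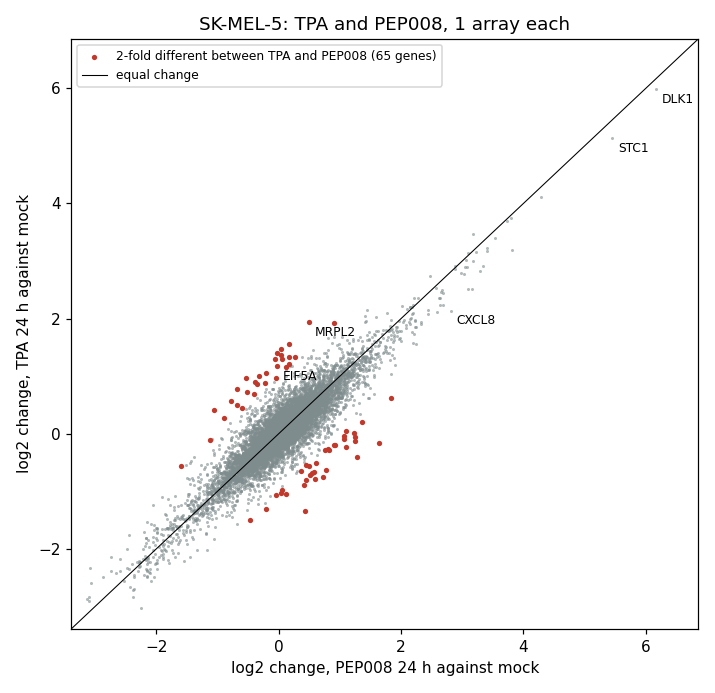
Log2 change against mock in SK-MEL-5 of each tested gene with 24 h of PEP008 (horizontal axis) and 24 h of TPA (vertical axis), 1 array each, with the line of equal change. DLK1 lies at 6.16 and 5.99, and the 65 genes that differ at least 2-fold between the compounds are marked.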

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

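The test of dim signal for the TPA and PEP008 differences and the scaling to the hybridisation controls were chosen only after the result was seen. Where values of different lines are set side by side, the difference was not tested, since each line had 1 array per condition.

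In the list of ATF4 and unfolded protein response genes 10 of 15 members were higher than mock in MCF7 and lower in COLO-205 at 24 h. At 24 h the median log2 change of the list was 0.88 in MCF7 and -1.33 in COLO-205, and after recovery it was 0.61 in SK-MEL-5, 1.61 in MCF7 and -1.23 in COLO-205. From 24 h to recovery it was 0.80 in SK-MEL-5, 0.49 in MCF7 and -0.29 in COLO-205. The stress sensor SESN2 had a signal in MCF7 of 138 in mock, 1799 at 24 h and 1647 after recovery, whereas in COLO-205 the transcription factor DDIT3 went from 1059 to 173 and 163, and asparagine synthetase, ASNS, from 3089 to 1109 and 641. At 24 h HSPA5 (0.88 in MCF7 and 0.35 in COLO-205), DNAJB9 (1.21 and 0.80), HERPUD1 (0.56 and 0.33) and PPP1R15A (1.12 and 0.78) were higher than mock in both lines, and XBP1 was lower in both (-1.82 and -0.47).

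Noise of single probe sets is an unlikely source of that split: 7 of the 15 members had another probe set, all 7 had a higher change in MCF7 than in COLO-205, and their median MCF7 minus COLO-205 change was 2.81 at 24 h and 3.12 after recovery. Array scaling is unlikely as well, as the gap between the list medians was 2.73 and 3.02 after scaling to the hybridisation controls. A COLO-205 mock culture that was itself under nutrient or protein stress could give the fall in that line, though not the rise in MCF7. Members differed on protein stress in it: HSPA5, DNAJB9, HERPUD1 and PPP1R15A were lower in that mock than at 24 h, while DDIT3 and XBP1 were higher. With 0 further mock arrays of MCF7 or COLO-205, the state of a mock culture cannot be told apart from a response to the drug. More mock cultures of both lines, with DDIT3 and ASNS measured by PCR, would separate them.

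Many cytokine and NF-kB genes stood higher after recovery than at 24 h in SK-MEL-5. The median log2 change from 24 h to recovery of the secreted factors was 2.01 in SK-MEL-5 and -0.54 in COLO-205, and that of the NF-kB targets was 0.88 and -0.42. CXCL8 differed by 5.10 in SK-MEL-5 and -1.26 in MCF7, IL6 by 2.76 and -1.35, and EGR1 by 2.35 and -1.87. The median of integrins and cell adhesion was 0.29 in SK-MEL-5 and -0.18 in COLO-205.

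Noise of single probe sets is unlikely here. The lists share genes such as CXCL8 and IL6, and 34 genes were in either list. Of these 15 were at least 2-fold higher, 5 of the 15 had another probe set, and all 5 were higher, with a median of 3.44. Over all 15 members with another probe set, chosen without regard to their change, 12 were higher, with a median of 0.93. Immune cells in the culture are also unlikely, since the highest signal of PTPRC, CD14 and CD3E on the SK-MEL-5 recovery array was 17.1, below the minimum of 70.1. Of other cell markers, PECAM1 (308, against 103 at 24 h) and DCN (583, against 149.9) were higher on that array. The endothelial markers CDH5 and VWF read 2.30 and 7.83, and the fibroblast markers COL1A2, COL3A1 and PDGFRB 1.41, 1.30 and 6.67. The longer time in culture, with cells at another density and in medium of another age, could raise such genes, and with 0 mock arrays of the recovery time it cannot be told apart from a late effect of the drug. A mock culture kept for the same 72 h would answer this.

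Medians of cell division genes moved in different directions between lines after drug removal, and their levels against mock came closer together. From 24 h to recovery the DNA replication median was -0.21 in SK-MEL-5, -0.40 in MCF7 and 1.15 in COLO-205, and the mitosis median was 0.19, -0.66 and 1.21 in the same order. LMNB1 differed by -1.23 in MCF7 and 1.46 in COLO-205, and it was also lower in SK-MEL-5, unlike the mitosis median of that line. The COLO-205 values came from a deeper 24 h level. Against mock the DNA replication medians at 24 h were -1.41 in SK-MEL-5, -1.10 in MCF7 and -2.92 in COLO-205. All 3 lines ended between -1.59 and -1.69 against mock for DNA replication.

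MITF, known as a regulator of pigment cells, had log2 changes at 24 h of 3.13 in MCF7 and -1.19 in COLO-205, and after recovery of -1.07 in SK-MEL-5, 3.11 in MCF7 and -1.06 in COLO-205. The COLO-205 signals of 36.6, 7.11 and 9.17 in mock, at 24 h and after recovery were all below the minimum of 70.1, so no fall can be read from them. In MCF7 the signals were 23.2, 327 and 323.

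For TPA against PEP008, noise of single probe sets may be a source of the 65 genes that differed at least 2-fold, but too few genes had another probe set to decide. Of 16 with another probe set 9 went the same way, or 56.2% (exact binomial p = 0.804, 95% Clopper-Pearson interval 29.9% to 80.2%), and these other probe sets are the dimmer ones of each gene. Dim signal may also explain them, since 49 of the 65 were below the minimum mean signal on both arrays, or 75.4% against 9.24% of all tested genes. Replicate arrays of each compound would show whether MRPL2 and the other brighter genes differ.

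Some data were not analysed by gene. Of 11721 probe sets with no gene symbol 1295 reached the mean signal of 70.1 set for genes, and of these 7 were at least 2-fold higher and 14 lower in all lines at 24 h (0.432 and 0.318 expected), and 8 and 15 after recovery (0.582 and 0.364 expected). The control probe set for the 3' end of 18S ribosomal RNA had log2 changes against mock of 0.46 at 24 h and 0.49 after recovery in SK-MEL-5, 0.63 and 0.52 in MCF7, and 1.06 and 0.80 in COLO-205. The other 18S control probe sets did not follow in SK-MEL-5: the 5' one read 100.45 in mock, 85.3 at 24 h and 88.3 after recovery, and the middle one 84.6, 87.9 and 84.1. In COLO-205 they read 57.5, 162 and 243 at the 5' end and 45.9, 149 and 168 in the middle, and in MCF7 77.5, 160.1 and 106 at the 5' end and 122, 152 and 173 in the middle. A further control, for which the annotation gives no gene, read 315, 2761 and 637 at its 5' end in COLO-205. Its middle probe set read 729, 1720 and 1038 and its 3' one 1.69, 14.8 and 8.59. By this control the COLO-205 24 h array, which had the lowest cell division medians, read highest. The 18S 5' and middle probe sets of COLO-205 read highest after recovery instead. The cause was not tested.

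Of the 10 ways to split the 6 arrays of a comparison into 3 and 3, only the real split gave 161 genes at 24 h (1 of 10) and only the real split gave 30 after recovery (1 of 10), with 0 as the highest of the others. For recovery against 24 h every split gave 0 (10 of 10). Of these splits 4 part all pairs, and 10 splits are too few for a share under 0.05. In the other splits against mock the change with drug enters the residual spread, so their 0 calls say little about chance.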

How the results depend on the processing

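The number of genes that passed depended on the settings more than their direction did, and the cause was not tested. At 24 h the 161 genes became 4 with a pseudocount of 1, 270 with 64, 58 with no filter on dim genes, 107 with genes above the 75th percentile of signal, 281 with an intensity trend and 1 with only the 6 arrays of the comparison. Scaling to the hybridisation controls, chosen after the data were seen, gave 387, with 28 rises and 359 falls against 38 and 123. Leaving out 1 line, which also leaves fewer residual degrees of freedom, gave 0 to 2 genes: 2 without SK-MEL-5, 0 without MCF7.

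After recovery the 30 genes (15 rises and 15 falls) became 0 with a pseudocount of 1, 249 (79 and 170) with 64, 163 (56 and 107) with quantile normalization, 151 (35 and 116) with each array centred on its median, and 0 with no filter on dim genes. The mean of all probe sets gave 102 (37 and 65), the hybridisation controls 177 (39 and 138), an intensity trend 268 and only 6 arrays 212. Leaving out 1 line gave 0 in each case, 0 without SK-MEL-5 among them.

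Without the cell line block, which pairs the arrays of a line, 0 genes passed at 24 h and 0 after recovery, and the list tests of recovery against 24 h gave 5 calls instead of 3.

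Of the 31 genes named in the texts that passed at 24 h, 31 passed with each array centred on its median and 30 with the hybridisation controls, but 1 with a pseudocount of 1 and 0 with any line left out. S100A2, KIF11 and ASPM kept their direction throughout. Scaling to the hybridisation controls put the median change of all genes at -0.32 at 24 h, -0.22 after recovery and 0.11 between them, against -0.02, -0.02 and 0.01 as deposited, and centring on the median put it at -0.11 after recovery.

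Genes at least 2-fold in all 3 lines numbered 210 at 24 h and 110 above the 75th percentile, and 323 and 171 after recovery. With the hybridisation controls the rises and falls were 18 and 216 at 24 h, against 52 and 158, and 58 and 310 after recovery, against 100 and 223, and centring on the median gave 75 and 259 after recovery.

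Calls of lists went from 12 to 0 at 24 h, 16 to 0 after recovery and 3 to 0 between them with an estimated correlation in camera. Other settings gave 11 (above the 75th percentile) to 14 (hybridisation controls) at 24 h. Recovery had 10 above the 75th percentile, and 13 with a pseudocount of 1 or without _x_at probe sets. It had 14 with quantile normalization, no filter on dim genes, the mean of all probe sets or no cell line block. Recovery against 24 h had 5 with the mean of all probe sets, 2 with no filter on dim genes and 1 with the hybridisation controls (the lysosome list, without mitosis and p53 targets). It had 4 (without SK-MEL-5) to 13 (without COLO-205) with 1 line left out.

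Some list medians changed direction with 1 line left out. At 24 h p53 targets went from 0.36 to -0.05 without MCF7 and -0.07 without COLO-205, the lysosome list from 0.34 to -0.01 without COLO-205, and the ATF4 list from -0.22 to 0.28 without SK-MEL-5 and 0.53 without COLO-205. After recovery the ATF4 list went from -0.30 without MCF7 to 1.09 without COLO-205, and ribosomal proteins from -0.13 without MCF7 to 0.16 without COLO-205. From 24 h to recovery DNA replication went from -0.29 without COLO-205 to 0.63 without MCF7, mitosis from -0.20 without COLO-205 to 0.68 without MCF7, secreted factors from -0.47 without SK-MEL-5 to 0.79 without MCF7, and NF-kB targets from -0.47 without SK-MEL-5 to 0.70 without COLO-205.

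The 65 genes between TPA and PEP008 became 280 with a pseudocount of 1, 4 with 64, 623 with no filter, 11 above the 75th percentile, 38 with the mean of all probe sets and 0 in limma with the residual spread of the 9-array fit.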

Other observations

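Some gene families outside the fixed lists had large median changes in a line. Each family was chosen after its values were seen, so no test is given, and near-identical members can share probe sequence. Histone genes (16 measured), many of which are normally made while DNA is copied, had a median log2 change after recovery of 1.15 in SK-MEL-5, 0.55 in MCF7 and 1.42 in COLO-205. Members differed: 9 were at least 2-fold higher and 0 lower in SK-MEL-5, 4 and 2 in MCF7, and 11 and 1 in COLO-205. At 24 h the median was 0.59 in SK-MEL-5 (6 at least 2-fold higher, 0 lower), 1.92 in COLO-205 (11 and 1) and -1.06 in MCF7 (0 and 10). H2AC6, a histone H2A gene, had a signal of 145 in mock, 729 at 24 h and 1388 after recovery in SK-MEL-5, 887, 237 and 2014 in MCF7, and 497, 3705 and 3144 in COLO-205 (log2 change after recovery 2.31 ± 0.79, n = 3 lines, adjusted p = 0.151). The sign of each of these medians was the same after quantile normalization, median centring and scaling to the hybridisation controls, and that of SK-MEL-5 at 24 h, 0.59, was 0.16 under the last. Where histone medians were higher than mock, DNA replication medians were lower: -1.41 in SK-MEL-5 and -2.92 in COLO-205 at 24 h. After recovery they were -1.59 in SK-MEL-5, -1.62 in MCF7 and -1.69 in COLO-205. As far as those genes report DNA copying, this argues against more of it as the source of the histone rises. In MCF7 at 24 h both were lower, with -1.10 for DNA replication.

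Metallothioneins, which bind zinc and copper (6 measured), stood higher in SK-MEL-5 (median 2.67 at 24 h and 3.49 after recovery) and MCF7 (1.94 and 2.46), with all 6 at least 2-fold higher. In COLO-205 the medians were -0.80 and -0.04. MT2A went from a signal of 796 to 6764 and 10592 in SK-MEL-5, from 440 to 2327 and 3646 in MCF7, and from 523 to 286 and 686 in COLO-205. Scaling to the hybridisation controls left the COLO-205 medians at -1.25 and -0.33.

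Genes known from other tissues were higher in 1 or 2 of the lines. Pregnancy-specific glycoproteins, made in placenta (5 measured), had a median of 0.69 in MCF7 at 24 h and 4.72 after recovery, with PSG6 at 41.2, 77.5 and 2543, against 0.63 in SK-MEL-5 and 0.14 in COLO-205 after recovery. Small proline-rich proteins, which form the envelope of squamous cells (4 measured), had a median in COLO-205 of 5.56 at 24 h and 4.29 after recovery, with SPRR1A at 378, 13395 and 6836, and in MCF7 of 1.496 and 1.85. S100A9, a calcium-binding alarmin, had signals in MCF7 of 28.1, 2252 and 7725 and in SK-MEL-5 of 18.4, 142 and 1757, but 4.59, 15.3 and 3.58 in COLO-205. The growth factor receptor gene EGFR was higher in all 3 lines after recovery, by 3.10 in SK-MEL-5, 2.81 in MCF7 and 2.08 in COLO-205 (2.66 ± 0.50, adjusted p = 0.0563).

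Mock arrays kept for 96 h, separate cultures of each line and TPA in MCF7 and COLO-205 would tell time from drug and line from array. Counting cells in S phase beside the histone transcripts would show whether those transcripts follow the share of cells in S phase.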
